A study of Mus musculus with 8 samples.

How the data were processed

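Total RNA was taken from the cortex of mouse embryos at E18.5 and sequenced on a NovaSeq X Plus, with 4 control libraries and 4 libraries labelled Upf2cKO. Per the labels' protocols, the libraries were made with a stranded kit sold for total RNA, while the same text describes a purification of mRNA and the labels call the molecule polyA RNA, so the kind of selection is uncertain. The submitters' processing notes name fastp 0.23.4, STAR 2.7.11a, Picard 3.1.1, MultiQC 1.25, DESeq2 and the build mm10, without saying what each did. The counting tool, its strand setting and the gene annotation are not given in the sources used here.

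The authors deposited 2 tables of 55487 genes by Ensembl identifier, a CPM table and a TPM table, each with 1 column per library and values rounded to 2 decimals. The deposited CPM columns each sum to the same total within rounding, as the unit requires, so they are relative to the reads assigned to genes with no further scaling factor. The deposited TPM columns do so too and are in addition divided by gene length. A CPM is a share of a library, so a rise of many genes lowers the values of the rest. Neither table holds raw counts. The value of 1 read was estimated from the steps between low values of short genes, for which the TPM resolves what the rounding of the CPM hides, from 30 to 102 values per library. Within a tolerance of 0.15 reads, 91.1% to 100.0% of those values came out whole, where chance gives 30.0%. The estimate of the depth was tested on simulated data and was off by at most 0.09%. Since 2 decimals are close to 1 read, whole reads were not recovered for all genes and no test on counts was run. At this depth the 0.5 CPM required of a tested gene stands for many reads, and the libraries of a group differed by more than the sampling of reads gives.

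Samples were grouped by the labels. Choices of test, samples, filters, alternatives, gene lists and the rule for named genes were made before the data were examined, except where the text says otherwise. Genes with at least 0.5 CPM in at least 4 of the 8 libraries were tested on log2(CPM + 0.1) with limma 3.58.1 (R 4.3.3), with an intensity trend, no covariate and a two-sided test, and p-values were adjusted by the Benjamini-Hochberg method over the 16573 genes kept, with a threshold of 0.05. Folds are on the log2(CPM + 0.1) scale, which understates the change of genes of low level. Upf2 was also compared by an exact permutation test. Adjusted p-values of single genes are limma's.

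Gene identifiers were matched to a GENCODE annotation of mm10, which gave a symbol to 55227 of 55487 identifiers and may differ from the annotation the authors used. Coordinates and gene classes are from it. Of the 112 genes that the rule for named genes takes, 53 overlap another annotated gene, 34 on the same strand and 36 on the other, and their values are uncertain to that extent, since how reads in overlaps and reads of several origins were counted is not given in the sources used here.

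The 13 gene lists were NMD factors, known NMD-sensitive transcripts, splicing factors with poison exons, the reelin pathway, motile cilia, primary cilium and intraflagellar transport, the hedgehog pathway, neuronal migration, p53 targets, the integrated stress and unfolded protein response, cell cycle, innate immune and interferon response, and synapse and neuronal maturation. The 19 marker lists covered radial glia, intermediate progenitors, upper-layer, deep-layer and subplate neurons, Cajal-Retzius cells, GABAergic interneurons, astrocytes, the oligodendrocyte lineage, microglia, endothelial cells, pericytes and mural cells, meningeal fibroblasts, erythroid cells, choroid plexus, striatum, thalamus and hypothalamus, hippocampus and cortical hem, and the mitochondrially encoded genes. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 32 lists, and again with an estimated correlation and with fry. Genes with an annotated NMD transcript and genes in the top 10% of 3' UTR length were compared with 10000 random lists of the same size, matched in 20 bins of mean log2 CPM, over the protein-coding genes.

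The genes named are Upf2; Reln, Dab1, Vldlr, Lrp8 and Foxj1; the 8 largest rises and the 8 largest falls among genes past the threshold, with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries, leaving out sex-linked genes, pseudogenes and predicted models; and from each list up to 3 members past the threshold with the smallest adjusted p, or its most abundant members. Gas5, Rfx3, Gadd45a, Eif4a2, Robo3, Slc7a11, Arc, Mdm2, P2ry12, Tmem119, Mobp, Mbp and Camk2a fall outside that rule, as do the values of single libraries given for Ttr, and were chosen after their values were seen.

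On simulated data with the level and spread of these libraries, 22% of genes changed 1.2-fold, 70% of those changed 1.5-fold, 92% of those changed 2-fold and all of those changed 4-fold were recovered, with 50 genes of each size among 16573. In the data 63% of genes changed. The unadjusted p that passes the threshold depends on that share, so these recoveries do not carry over to the reported comparison. Among the simulated calls 9% were false, and with no change simulated there were 0 calls, where 879 genes had an unadjusted p under 0.05. A shifted list was found and 0 of 29 unshifted lists were called. The simulated genes varied independently of each other, whereas the estimated correlation in the real lists reached 0.818 (astrocytes). The simulation therefore does not show how often lists of correlated genes are called falsely.

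The alternatives fixed beforehand were pseudocounts of 1 and 0.01 CPM, no filter, a filter of 2 CPM, rescaling by median-of-ratios size factors, the TPM table, sample quality weights, the replicate number as a block, leaving out each library in turn and, for the annotated classes, matching on gene length. Chosen after seeing the data were leaving out both libraries numbered 1, leaving out control 4 and Upf2cKO 4, covariates for the levels of Ttr and of Xist, which marks female embryos, matching on the number of transcripts, and the settings of the gene model for the annotated classes, with 1000 random lists each. Intervals of medians are 95% bootstrap intervals over genes. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.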

Results

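RNA from the cerebral cortex of mouse embryos late in gestation (E18.5) was sequenced in 8 libraries, 4 from controls and 4 labelled Upf2cKO. Upf2 is a core factor of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts with a premature stop codon. In the libraries labelled Upf2cKO, both floxed Upf2 alleles were combined with Emx1-Cre, a recombinase active in the dorsal forebrain progenitors that give rise to cortical excitatory neurons and glia. Of the 4 controls, 3 carried both floxed alleles and control 2 carried a single floxed allele, and no control carried the recombinase. The comparison asked which genes, and in particular which reelin and ciliary genes named in the title of the series, differed in the cortex of the conditional mutant. From the steps between low values, between 96.6 M and 156.0 M reads per library were estimated to have been assigned to genes. One read was therefore worth 0.0064 to 0.0104 CPM (read counts scaled to a common library total), well below the 0.5 CPM required of a tested gene. The labels do not say whether the embryos came from separate litters, so p-values measure the spread between these samples. Within a group no 2 libraries were identical. The squared differences between 2 libraries, as a median over genes, were 6.64 to 19.5 times what the sampling of reads alone gives.

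Upf2 itself was higher, not lower, in the libraries labelled Upf2cKO. Its level was 60.0, 58.1, 68.5 and 60.7 CPM in controls 1 to 4 and 135, 139, 142 and 154 CPM in Upf2cKO 1 to 4. The means were 61.8 ± 4.58 CPM (SD, n = 4) in controls and 143 ± 7.84 CPM (SD, n = 4) in Upf2cKO, a 2.31-fold difference on the log2(CPM + 0.1) scale. All 4 values of a group lay apart from those of the other (exact permutation test, two-sided, p = 0.0286, the smallest that 70 arrangements can give; limma adjusted p = 3.35e-08). Upf2 lies on chromosome 2 from 5951469 to 6056703 on the plus strand of mm10, and the deposited value is for the gene as a whole. How reads were counted over its exons is not given in the sources used here. A whole-gene total can include exons that were not deleted, so it checks neither the deletion nor the labels. Every direction below is for the libraries labelled Upf2cKO. Of 24 known NMD-sensitive transcripts, 19 were higher and 1 was lower in those libraries, which argues against swapped groups.

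Most of the expressed genes differed between the groups. Of 16573 genes tested, 10441 (63.0%) changed, 6082 of them higher and 4359 lower in Upf2cKO. Among changes of at least 2-fold, rises far outnumbered falls, with 1615 genes higher and 137 lower. The genes with the largest rises by the rule fixed beforehand were Trat1, a T cell receptor adaptor (0.285 ± 0.105 to 16.6 ± 2.81 CPM), Lyz1, a lysozyme (0.0175 ± 0.0222 to 3.65 ± 0.960), Mfsd7a, Clhc1, Snhg12, Serpinb6c, Trim72 and P2ry4, all at least 20.1-fold higher. The largest falls were in Nts, which encodes the neuropeptide neurotensin (104 ± 2.80 to 15.9 ± 3.12 CPM, 6.60-fold lower), Plpp2, Nlrp6, Aldh1a3, a retinoic acid synthesis enzyme, Tshz2, Msx3, Cck, which encodes cholecystokinin (3.33-fold lower), and Grp, which encodes gastrin-releasing peptide (3.26-fold lower). Except for Snhg12, the genes with the largest rises were close to absent in controls, at a mean of 0.285 CPM or less, so their folds depend on the pseudocount. With 1 CPM in place of 0.1, the log2 change of Lyz1 moved from 4.97 to 2.17 and that of P2ry4 from 4.33 to 1.73. The same setting moved the log2 change of Nlrp6 from -2.221 to -1.155, that of Aldh1a3 from -2.18 to -1.01 and that of Msx3 from -1.80 to -0.958. Lyz1 shares sequence with its neighbour Lyz2, and Clhc1 overlaps Rps27a on the other strand, so their values are uncertain.

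**Figure D1:**
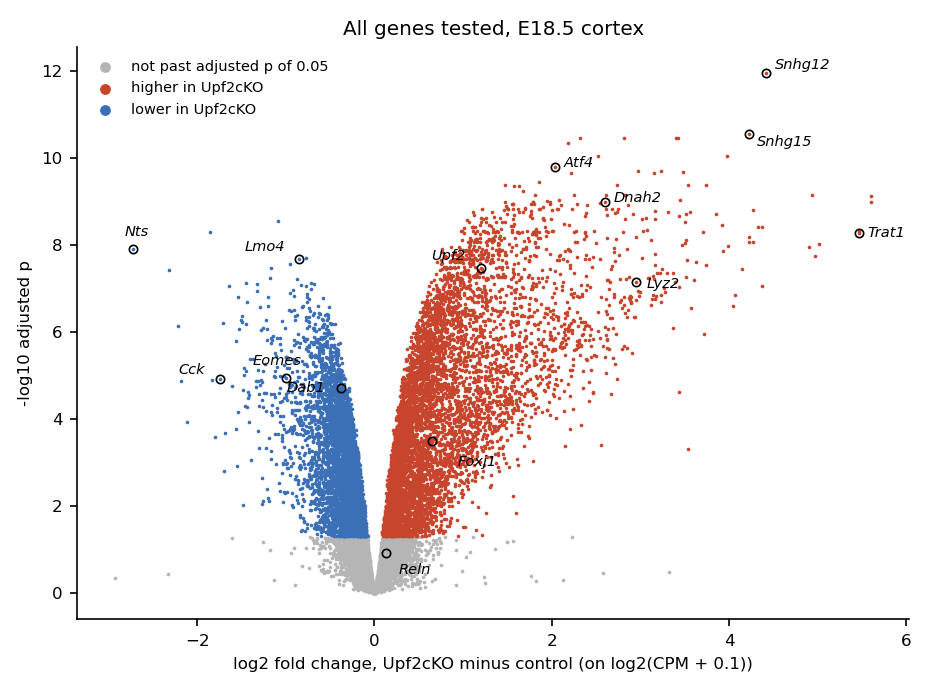
Log2 fold change of Upf2cKO over control on the log2(CPM + 0.1) scale (horizontal axis) against minus log10 of the limma adjusted p (vertical axis) for 16573 genes, with 4 libraries per group. Red points are the 6082 genes higher and blue points the 4359 genes lower in Upf2cKO at an adjusted p under 0.05, and the circles mark genes named in the text, with Snhg12 at the top and Reln among the grey points.

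The shift towards higher values was strongest among genes of low level and among non-coding genes. Under a mean of 1 CPM, 41.7% of 1754 genes were higher and 8.8% lower, whereas over 100 CPM 29.7% of 2558 genes were higher and 39.0% lower. Long non-coding RNAs were higher in 42.2% and lower in 13.5% of 1471 genes, pseudogenes in 42.1% and 13.4% of 484, and protein-coding genes in 36.2% and 28.5% of 14030. Of 588 genes of other classes or absent from the annotation, 30.8% were higher and 16.7% lower. The classes were not compared at the same level, so whether class adds to level was not tested. All values of a group lay beyond all values of the other in 56.6% of genes, where chance gives 2.86%. The first principal component took 76.1% of the variance and separated the groups. The second took 9.9% and set Upf2cKO 1 at 30.3, apart from the range of -20.9 to -1.1 of the other Upf2cKO libraries.

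Transcripts known as targets of NMD rose together. Of 24 known NMD-sensitive transcripts, 19 were higher and 1 was lower in Upf2cKO, with a median 3.07-fold rise (camera adjusted p = 2.71e-07, and adjusted p = 0.0413 with an estimated correlation). The small nucleolar RNA host gene Snhg12, on chromosome 4 from 132308623 to 132311024, went from 32.1 ± 1.54 to 690 ± 21.5 CPM (21.4-fold, SE of the log2 change 0.043, limma adjusted p = 1.09e-12), Snhg15 from 5.64 ± 0.318 to 107 ± 6.58 CPM (18.7-fold) and Epb41l4aos from 6.54 ± 0.2995 to 71.3 ± 3.35 CPM (10.7-fold). Gas5, the most abundant member of the list in Upf2cKO, rose from 168 to 1218 CPM. Gadd45a was the member that fell, from 2.36 to 1.97 CPM (adjusted p = 0.0393), and the values of Eif4a2, Robo3, Slc7a11 and Arc did not pass the test. The reads of Snhg12, Snhg15 and Epb41l4aos may be shared with small nucleolar RNAs annotated within them, since the counting is not given in the sources used here.

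The factors of the NMD pathway moved in both directions. Of 22 members, 13 were higher and 7 lower, and as a group they did not pass (camera adjusted p = 0.114), except with no filter on low values (adjusted p = 0.0191). On TPM the number lower was 4. The helicase Dhx34 rose from 16.4 ± 0.767 to 43.5 ± 3.099 CPM (2.63-fold), and Smg9 (2.44-fold) and Smg5 (1.90-fold), which take part in the phosphorylation cycle of Upf1, rose too. Of 24 splicing factors whose genes carry poison exons, 15 were higher and 6 lower (median 1.24-fold, camera adjusted p = 0.0463, but adjusted p = 0.721 with an estimated correlation). Tra2b rose from 225 ± 7.45 to 475 ± 29.8 CPM (2.11-fold), Luc7l 1.94-fold and Srsf3 1.91-fold. That group's call was lost without control 2 (adjusted p = 0.0524), control 4 (0.0583), Upf2cKO 3 (0.0717) or Upf2cKO 4 (0.0809), with median-of-ratios rescaling (0.0591) and, in a setting chosen after seeing the data, without control 4 and Upf2cKO 4 (0.0931).

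Genes with an annotated NMD transcript were higher more often than other genes of the same level. Among 14030 protein-coding genes, the 3884 with such a transcript had a median log2 change of 0.14, against 0.01 in random lists matched on level (permutation p = 1e-04, the smallest that 10000 lists can give), and 47.9% of them were higher, against 35.4%. Genes with many annotated transcripts were also higher more often: matched on the number of transcripts as well, in a setting chosen after seeing the data, the random lists had a median of 0.07 and 41.0% higher genes. Genes in the top 10% of annotated 3' UTR length, at 3765 nucleotides or more, had a median of -0.06 against -0.01 (permutation p = 1e-04) and 26.2% higher against 33.8%, over 1404 of 14011 genes. Without control 1, the difference between the long 3' UTR genes and the random lists went from -0.05 to -0.03, and matched on gene length it was -0.11. Of the 35 ways to split the libraries into 4 and 4, 4 gave a difference of this size or more for the long 3' UTR genes.

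**Figure D2:**
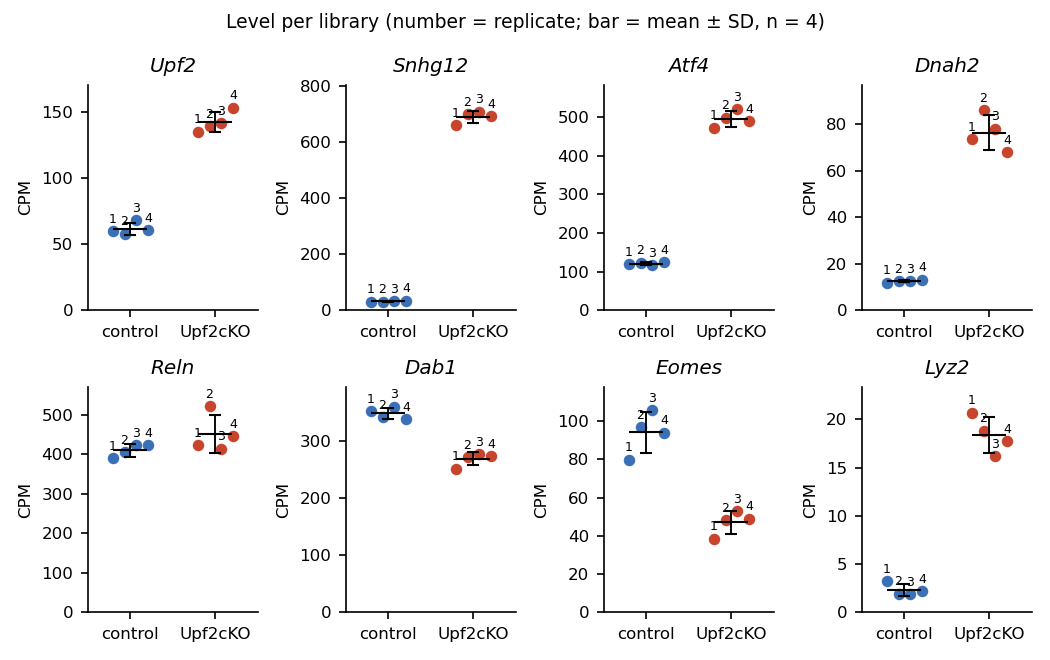
CPM (vertical axis, from 0) of 8 genes in each library, by group (horizontal axis), with the replicate number above each point and bars at the mean ± SD of the 4 libraries. Upf2, Snhg12, Atf4, Dnah2 and Lyz2 were higher and Dab1 and Eomes lower in every Upf2cKO library than in any control, while the values of Reln overlapped.

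Within the reelin pathway, which guides the layering of cortical neurons, Dab1 and Lrp8 fell, whereas Reln and Vldlr did not pass the test. Reln had 411 ± 16.1 CPM in controls and 452 ± 49.0 in Upf2cKO (1.096-fold, adjusted p = 0.119). Of its receptors, Vldlr had 130 ± 0.860 and 135 ± 4.53 CPM (1.03-fold, adjusted p = 0.263). The receptor Lrp8 fell from 359 ± 6.26 to 296 ± 11.7 CPM (1.22-fold lower, adjusted p = 9.23e-05), and Dab1, the adaptor that carries the signal into the cell, fell from 349 ± 9.90 to 269 ± 11.4 CPM (1.30-fold lower, adjusted p = 1.9e-05). In the list of 30, 4 genes were higher and 16 lower (camera adjusted p = 0.00484, but adjusted p = 0.101 with an estimated correlation). The counts moved with the scaling, to 7 higher and 10 lower on TPM and 3 higher and 21 lower after median-of-ratios rescaling. Nectin3, an adhesion molecule of migrating neurons, was 1.46-fold lower and the ephrin Efnb2 1.29-fold higher. On the deposited TPM, Reln (adjusted p = 0.0289) and Vldlr (adjusted p = 0.0323) passed the test as higher, and the list's median log2 change went from -0.15 to -0.09. After median-of-ratios rescaling, Vldlr had a log2 change of -0.01 (adjusted p = 0.879).

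Of 44 neuronal migration genes, 9 were higher and 21 lower (camera adjusted p = 0.0017, but adjusted p = 0.101 with an estimated correlation). Their median log2 change was -0.15, and -0.09 on TPM. On TPM 9 were higher and 18 lower, and after median-of-ratios rescaling 8 were higher and 27 lower. The change with the smallest p ran against the rest: Flna, which encodes filamin A, rose from 310 ± 10.7 to 1020 ± 110 CPM (3.28-fold, adjusted p = 1.09e-08). The guidance factor Sema3c fell from 148 ± 11.1 to 81.5 ± 6.36 CPM (1.81-fold lower) and the receptor Unc5d from 106 ± 2.35 to 73.3 ± 5.89 CPM (1.44-fold lower).

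Ciliary genes rose as groups. Of 42 motile cilia genes measured, 31 were higher and 3 lower, with a median 1.71-fold rise (camera adjusted p = 6.73e-05, but adjusted p = 0.216 with an estimated correlation). The smallest adjusted p-values in the list were those of axonemal dynein heavy chains. Dnah1 went from 4.12 ± 0.207 to 25.6 ± 1.31 CPM (6.09-fold), Dnah2 from 12.5 ± 0.489 to 76.4 ± 7.71 CPM (6.06-fold) and Dnah9 from 5.13 ± 0.545 to 33.4 ± 1.61 CPM (6.42-fold). Foxj1, the master regulator of motile cilia, rose from 6.99 ± 1.12 to 10.9 ± 0.412 CPM (1.57-fold, SE of the log2 change 0.106, adjusted p = 0.000317), while the most abundant member, Rfx3, a transcription factor of ciliary genes, fell from 148 to 111 CPM. The level of Ttr, a marker of the choroid plexus, whose epithelium carries motile cilia, differed widely between libraries. It stood at 119 CPM in control 4 and 258 CPM in Upf2cKO 4, at 28.5 CPM in control 1, and between 1.37 and 4.40 CPM in the other 3 Upf2cKO libraries. Without control 4 and Upf2cKO 4, a setting chosen after seeing the data, 30 motile cilia genes were higher and 3 lower.

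Of 68 genes of the primary cilium and intraflagellar transport, 41 were higher and 8 lower, with a median 1.23-fold rise (camera adjusted p = 0.00074, but adjusted p = 0.101 with an estimated correlation). Ift172, a subunit of the transport complex, rose from 52.1 ± 2.35 to 123 ± 7.73 CPM (2.36-fold), Invs, the gene of inversin, 2.62-fold and the BBSome subunit Bbs7 1.67-fold. Of the 68, the number lower was 5 on TPM and 11 after median-of-ratios rescaling. The hedgehog pathway, which signals through the primary cilium, had 3 of 11 genes higher and 3 lower and did not pass as a group (camera adjusted p = 0.756). Without control 2 the number lower was 1. Of the co-receptors, Cdon rose from 88.9 ± 5.32 to 241 ± 17.8 CPM (2.71-fold) and Gas1 was 1.45-fold lower, and the receptor Ptch1 was 1.26-fold higher.

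Stress-response genes were higher. Of 34 genes of the integrated stress and unfolded protein responses, 22 were higher and 2 lower, with a median 1.33-fold rise (camera adjusted p = 0.000476, but adjusted p = 0.216 with an estimated correlation). The transcription factor Atf4, itself among the known NMD-sensitive transcripts, rose from 121 ± 3.41 to 496 ± 20.1 CPM (4.11-fold, SE of the log2 change 0.04), its target Cars, a cysteinyl-tRNA synthetase, from 54.0 ± 1.36 to 150 ± 0.670 CPM (2.78-fold), and Ddit3, also on both lists, 3.93-fold. Of 29 p53 targets, 22 were higher and 2 lower, with a median 1.48-fold rise (camera adjusted p = 0.000812, but adjusted p = 0.216 with an estimated correlation). The death receptor Tnfrsf10b rose from 1.13 ± 0.0841 to 6.21 ± 0.270 CPM (5.13-fold), Eda2r 6.62-fold and the non-coding RNA Pvt1 5.24-fold. Mdm2, a feedback inhibitor of p53 chosen after its values were seen, had 57.5 and 55.1 CPM (adjusted p = 0.386). Of 25 innate immune and interferon genes, 13 were measured, with 5 higher and 2 lower, and they did not pass as a group (camera adjusted p = 0.49). Of all tested genes, 36.7% were higher and 26.3% lower. The interferon-response factors Irf9 (2.51-fold), Stat2 (1.76-fold) and Irf7 (2.51-fold) were higher.

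Cell cycle genes were lower in 23 and higher in 4 of 40 (median log2 change -0.25, camera adjusted p = 0.000624, but adjusted p = 0.608 with an estimated correlation). The DNA clamp Pcna fell from 106 ± 2.56 to 68.5 ± 3.02 CPM (1.55-fold lower), whereas the helicase subunit Mcm7 (2.42-fold) and the thymidylate synthase Tyms (1.81-fold) rose. Mcm7 overlaps Ap4m1 on the other strand. Of 37 genes of synapse and neuronal maturation, 10 were higher and 15 lower (camera adjusted p = 0.0461, but adjusted p = 0.721 with an estimated correlation). The growth cone protein Gap43 fell from 635 ± 38.5 to 392 ± 14.7 CPM (1.62-fold lower), the glutamate receptor Gria2 1.61-fold and the splicing regulator Rbfox1 1.54-fold. The synaptic list's call was lost without control 1 (adjusted p = 0.0655), Upf2cKO 2 (0.0520), Upf2cKO 3 (0.0745) or Upf2cKO 4 (0.102) and with a filter of 2 CPM (0.0889), or without control 4 and Upf2cKO 4 (0.0904), and its median log2 change went from -0.14 to -0.08 on TPM. On TPM 11 of its genes were higher and 12 lower, and after median-of-ratios rescaling 8 were higher and 19 lower. Without Upf2cKO 1 the number lower was 21. Upf2cKO 1 held 339 CPM of Camk2a, a kinase of mature neurons, against 41.5 to 45.2 CPM in the other Upf2cKO libraries.

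Markers of the cells in which Emx1-Cre is active were mostly lower. Of 20 radial glia markers, 14 were lower and 0 higher (median log2 change -0.42, camera adjusted p = 1.61e-05, but adjusted p = 0.263 with an estimated correlation), among them Nes (204 ± 5.72 to 132 ± 5.19 CPM, 1.55-fold lower), Fabp7 (1.59-fold lower) and Emx2 (1.64-fold lower). Upper-layer neuron markers were lower in 15 and higher in 2 of 18 (median log2 change -0.55, camera adjusted p = 1.61e-05, but adjusted p = 0.213 with an estimated correlation). Lmo4 fell from 227 ± 7.97 to 126 ± 3.47 CPM (1.81-fold lower), Pou3f3 1.752-fold and Cux1 1.42-fold. Deep-layer markers were lower in 10 and higher in 2 of 17 (camera adjusted p = 0.0168, but adjusted p = 0.288 with an estimated correlation), with Ntsr1 2.01-fold, Hs3st4 1.67-fold and Ldb2 1.504-fold lower. On TPM 8 deep-layer markers were lower and 4 higher, and after median-of-ratios rescaling 11 were lower and 0 higher. Without Upf2cKO 1, 10 were lower and 4 higher. Eomes, the transcription factor that defines intermediate progenitors, fell from 94.2 ± 10.8 to 47.1 ± 6.08 CPM (2.00-fold lower, adjusted p = 1.1e-05), and Rhbdl3 and Insm1 each fell 1.41-fold. Their list of 11, with 2 higher and 4 lower, did not pass (camera adjusted p = 0.114). It passed without control 1 (adjusted p = 0.0364), without both libraries numbered 1 (0.0374) and with the replicate block (0.0489).

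The lists for neurons that settle outside the cortical plate did not pass. Subplate markers were higher in 4 and lower in 3 of 10 (camera adjusted p = 0.756), with Nxph4 1.79-fold and Nr4a2 1.252-fold higher and Hs3st2 1.76-fold lower. Of 12 markers of Cajal-Retzius cells, the reelin-producing cells of the cortical surface, 8 were higher and 2 lower (camera adjusted p = 0.299), with Trp73 1.48-fold and Nhlh2 1.52-fold higher.

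**Figure D3:**
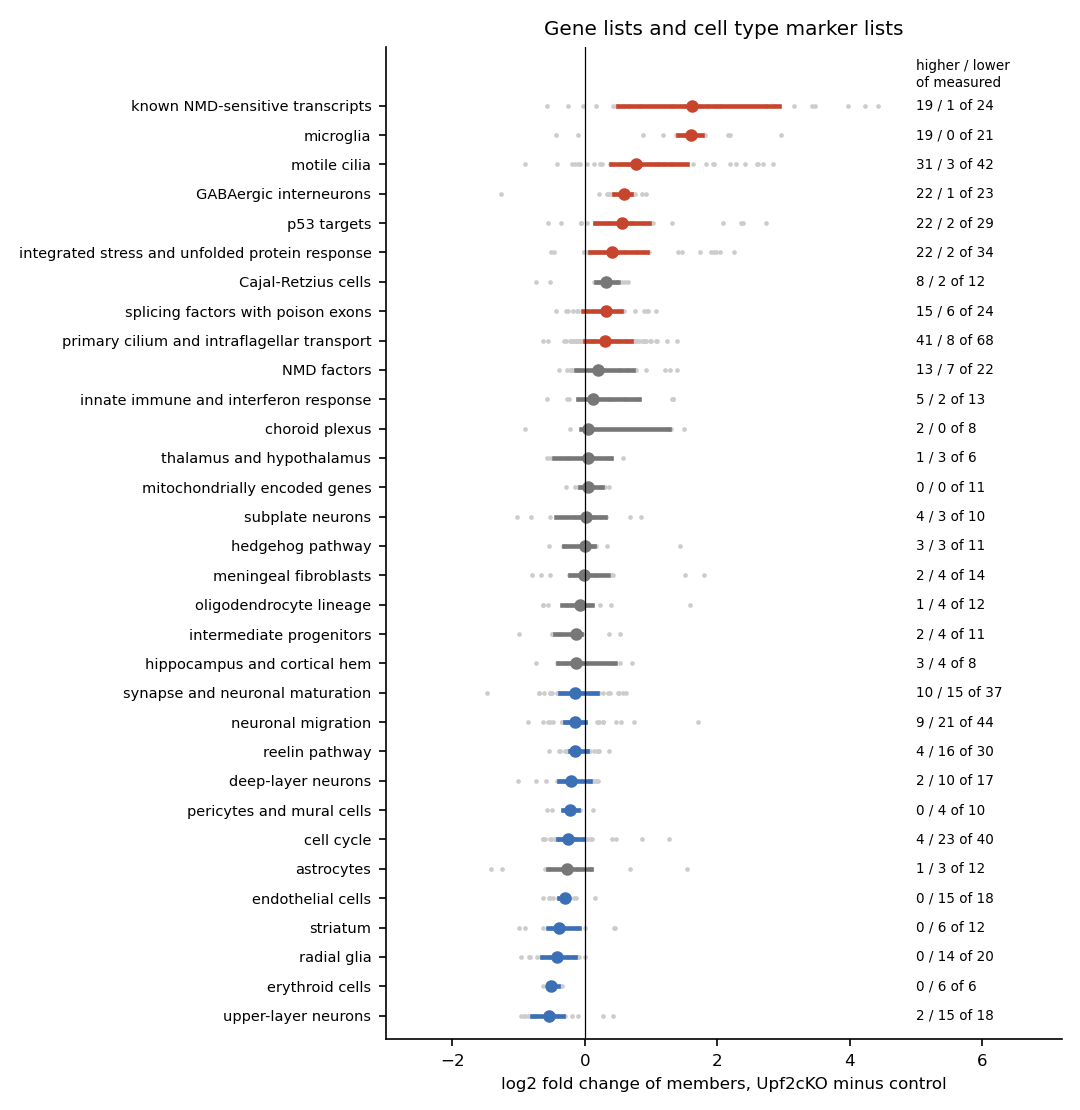
Log2 fold change of Upf2cKO over control (horizontal axis) for the measured members of 32 gene and marker lists (vertical axis), with grey points for genes, bars from the lower to the upper quartile and large points at the median. Lists past a camera adjusted p of 0.05 with the preset correlation are red (8 higher) or blue (11 lower), the others are grey, and the numbers at the right count members higher and lower of those measured.

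Markers of cells outside the Emx1 lineage moved apart. Of 23 GABAergic interneuron markers, 22 were higher, with a median 1.51-fold rise (camera adjusted p = 0.000476, but adjusted p = 0.396 with an estimated correlation). Adarb2 rose from 21.6 ± 0.464 to 35.6 ± 1.54 CPM (1.64-fold) and the transcription factor Lhx6 1.62-fold, while the neuropeptide gene Npy alone fell, from 64.5 ± 5.22 to 26.9 ± 3.82 CPM (2.40-fold lower). Of 21 microglia markers, 19 were higher and 0 lower, with a median 3.03-fold rise (camera adjusted p = 1.61e-05, but adjusted p = 0.416 with an estimated correlation). Lyz2 rose from 2.33 ± 0.643 to 18.4 ± 1.88 CPM (7.75-fold), the chemokine receptor Cx3cr1 from 9.95 ± 0.745 to 30.2 ± 3.60 CPM (3.00-fold) and the lysosomal protein Cd68 3.06-fold. The remaining members of the microglia list, P2ry12 (4.77 and 4.58 CPM, adjusted p = 0.697) and Tmem119 (1.19 and 0.935 CPM, adjusted p = 0.219), did not pass.

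The endothelial, pericyte and erythroid lists passed as lower with the preset correlation, though not every endothelial or pericyte marker passed. Of 18 endothelial markers, 15 were lower and 0 higher (median log2 change -0.30, camera adjusted p = 0.000125, but adjusted p = 0.216 with an estimated correlation), with Cldn5, a tight junction protein, 1.39-fold, Kdr 1.32-fold and Erg 1.44-fold lower. Of 10 pericyte and mural cell markers, 4 were lower (camera adjusted p = 0.0347, but adjusted p = 0.216 with an estimated correlation), among them Myl9 (1.49-fold), Pdgfrb (1.252-fold) and Higd1b (1.41-fold). After median-of-ratios rescaling 7 of the 10 were lower, and without Upf2cKO 1, 6 were. The call was lost with a filter of 2 CPM (adjusted p = 0.0604). All 6 erythroid markers measured were lower (camera adjusted p = 0.0109, but adjusted p = 0.331 with an estimated correlation), with Tfrc 1.40-fold, Hba-a1 1.46-fold and Hbb-bt 1.54-fold lower. The globins are uncertain because near-identical copies share reads. Meningeal fibroblast markers were higher in 2 and lower in 4 of 14 (camera adjusted p = 0.666), with Dcn 3.47-fold and Crabp2 2.84-fold higher and Col5a1 1.58-fold lower. The balance turned without control 4, when 4 were higher and 2 lower. With a pseudocount of 1 CPM the log2 change of Crabp2 went from 1.51 to 0.789.

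The astrocyte and oligodendrocyte lineage lists did not pass with all 8 libraries. Astrocyte markers were higher in 1 and lower in 3 of 12 (camera adjusted p = 0.148), with Slc6a11 2.68-fold and Sparcl1 1.51-fold lower and the lipid carrier Apoe 2.92-fold higher. Upf2cKO 1 stood apart for these genes: Slc6a11 was at 42.1 CPM there and 24.5 to 25.1 CPM in the other Upf2cKO libraries, and without that library 8 of the 12 markers were lower, their median log2 change went from -0.28 to -0.44 and the list passed as lower (adjusted p = 0.00274), as it did without both libraries numbered 1 (0.0042) and with sample quality weights (0.0316). Oligodendrocyte lineage markers were higher in 1 and lower in 4 of 12 (camera adjusted p = 0.25), with Olig2 1.48-fold and Olig1 1.55-fold lower. Mbp, a myelin gene outside the lists, was at 225 CPM in Upf2cKO 1 and 16.1 to 17.8 CPM in the other Upf2cKO libraries, and at 65.5 CPM in control 1 and 28.6 to 34.0 CPM in the other controls.

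**Figure D4:**
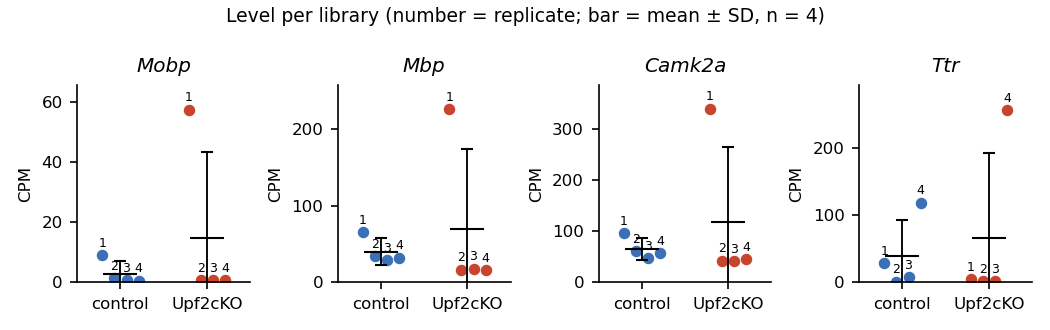
CPM (vertical axis, from 0) of the myelin genes Mobp and Mbp, the neuronal gene Camk2a and the choroid plexus gene Ttr in each library, by group (horizontal axis), with the replicate number above each point and bars at the mean ± SD of the 4 libraries. Upf2cKO 1 held 57.4 CPM of Mobp where the other Upf2cKO libraries held 0.68 to 0.75, and Ttr was highest in control 4 and Upf2cKO 4.

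Markers of neighbouring brain regions were examined because a dissection can include them. Striatal markers were lower in 6 and higher in 0 of 12 (camera adjusted p = 0.0292, but adjusted p = 0.592 with an estimated correlation), with Ppp1r1b 2.00-fold and Rgs9 1.44-fold lower. The striatal median log2 change of -0.39 was -0.25 with a pseudocount of 1 CPM and -0.23 with no filter on low values. Thalamic and hypothalamic markers were higher in 1 and lower in 3 of 6 (camera adjusted p = 0.49), with Slc17a6 1.49-fold and Calb2 1.44-fold lower and Lef1 1.32-fold higher. Their median log2 change was 0.05 and their mean -0.01. The balance turned without control 2, when 3 were higher and 2 lower. Markers of hippocampus and cortical hem were higher in 3 and lower in 4 of 8 (camera adjusted p = 0.49), with Nrp2 1.64-fold higher and Rspo2 1.67-fold and Zbtb20 1.32-fold lower. Of 8 choroid plexus markers, 2 were higher (camera adjusted p = 0.732), Rdh5 2.46-fold and Slc4a5 2.39-fold. With a pseudocount of 1 CPM their log2 changes went from 1.295 to 0.832 and from 1.26 to 0.480. None of 11 mitochondrially encoded genes passed (camera adjusted p = 0.756; 0 at an unadjusted p under 0.05), though 3 were higher without control 1 and 2 were lower after median-of-ratios rescaling, and these genes took 1.55% to 2.08% of each library. Without control 4 and Upf2cKO 4, the striatal (adjusted p = 0.0679, median log2 change -0.21) and pericyte (adjusted p = 0.0679) calls were lost.

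In total, 19 of 32 lists passed with the preset correlation, 8 higher and 11 lower, and 1 passed with a correlation estimated from these libraries, the known NMD-sensitive transcripts. Fry, which asks whether a list's own genes move one way without comparing them with other genes, called 22. The signs of the median, the mean, camera or fry differed for 5 of the lists that did not pass: the hedgehog pathway, subplate neurons, meningeal fibroblasts, thalamus and hypothalamus, and the mitochondrially encoded genes. Adjusted over the list alone, the counts of members higher and lower were those given above except in 6 lists: the reelin pathway (4 higher and 17 lower), the primary cilium (41 and 9), neuronal migration (9 and 22), synapse and neuronal maturation (10 and 19), the oligodendrocyte lineage (1 and 3) and endothelial cells (0 and 16).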

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

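All tests of explanations in this part were chosen after the values they bear on had been seen. Within each group of 4 libraries, values were examined for a library set far from the other 3, by the gap to its neighbour against the whole range. This was done for 126 genes and 3 library measures, in 258 groups, of which chance sets apart about 1 in 20, or 12.9. It set apart 24, of which 10 were in Upf2cKO 1, 6 in control 1, 3 each in control 3 and Upf2cKO 4, and 2 in control 2. Mobp, Mbp, Camk2a and Ttr were among the genes examined because their values had been seen.

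Transcripts of mature brain stood out in Upf2cKO 1 and, at lower levels, in control 1. Mobp was at 57.37 CPM in Upf2cKO 1, where the other Upf2cKO libraries held 0.68 to 0.75, and at 9.09 CPM in control 1, where the other controls held 0.54 to 1.38. Mbp was at 225.2 and 65.49 CPM in these libraries. Camk2a was at 339.3 CPM in Upf2cKO 1, Slc6a11 at 42.07, Apoe at 357.2 against 207 to 231.4, Zbtb20 at 195.9 against 162.4 to 166.3, and Cck at 11.69 against 6.51 to 7.19. In all, 256 genes were more than 2-fold above every other Upf2cKO library in Upf2cKO 1, against 3, 7 and 10 such genes in Upf2cKO 2, 3 and 4. Of 52 markers of mature brain, 46 passed the filter on level in these libraries.

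For this pattern, RNA of mature brain tissue in Upf2cKO 1 is a candidate explanation. Of 52 mature markers, 96.2% had their highest Upf2cKO value there, including 16 of 17 for myelin, 13 of 13 for astrocytes and 21 of 22 for neurons, where chance gives 25%, and 41 of 52 had their highest control value in control 1. Whether an older embryo adds to it stays open, since in that library the 11 intermediate progenitor genes were lower than in the other 3 (median log2 difference -0.104, interval -0.347 to -0.041) but the 40 cell cycle genes were not (0.046, interval 0.024 to 0.112), and in control 1 both were lower (-0.225 and -0.108). Loss of Upf2 was argued against by the other Upf2cKO libraries, since without both libraries numbered 1 the markers had a median log2 change of -0.081 (interval -0.205 to 0.086, 46 genes). How such RNA may have entered, during dissection, library preparation or sequencing, stays open.

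The remaining values set apart are given without an explanation. In Upf2cKO 1, Plpp2 was at 1.42 CPM against 1.05 to 1.08, Hs3st4 at 45.7 against 53.63 to 54.62 and Rdh5 at 1.97 against 2.57 to 2.67. In Upf2cKO 4, Ttr was at 257.5 CPM against 1.37 to 4.4, Slc4a5 at 1.52 against 0.6 to 0.62 and Ift172 at 111.7 against 125.4 to 128.2. In control 1, Insm1 was at 57.72 CPM against 67.07 to 68.25, Pvt1 at 3.28 against 2.66 to 2.74, Pdgfrb at 23.97 against 25.25 to 25.38 and Crabp2 at 0.33 against 0.54 to 0.57. In control 2, the control with a single floxed allele, Nlrp6 was at 2.48 CPM against 1.84 to 1.92 and Sema3c at 164.3 against 141.2 to 143.7. In control 3, Fabp7 was at 531.6 CPM against 576.8 to 582, Hs3st2 at 11.14 against 13.01 to 13.34 and Csf1r at 11.33 against 13.71 to 14.05.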

How the results depend on the processing

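The settings that left out both libraries numbered 1 or control 4 and Upf2cKO 4, the Ttr and Xist covariates, the matching on transcript number and the gene model settings of the annotated classes were chosen after seeing the data. Leaving out each library in turn gave 9651 to 10660 changed genes, 5747 to 5999 higher and 3886 to 4661 lower, and 17 to 20 lists. These settings gave a log2 change of Upf2 of 1.17 to 1.26, a difference from random lists of 0.133 to 0.143 for genes with an annotated NMD transcript and of -0.061 to -0.033 for long 3' UTR genes. Over the other 12 settings of the gene model there were 8947 to 11656 changed genes, 4864 to 7515 higher and 3368 to 5257 lower. The number of lists stayed within 15 to 22 except with an estimated correlation, where it was 1. A higher correlation was not the cause in every list. It was estimated at -0.007 for the reelin pathway, 0.006 for neuronal migration and 0.006 for the primary cilium, below the preset 0.01. Their unadjusted camera p still rose, from 0.00197 to 0.0126, from 0.000636 to 0.0111 and from 0.000231 to 0.00704. In other lists the estimate was well above the preset, as in microglia (0.637). The cause was not tested further. No gene called in the reported comparison changed sign in any of these settings while called in both. Without both libraries numbered 1, 10435 genes changed, 5965 higher and 4470 lower. Of the 10441 reported calls, 9747 were shared. The median log2 change of all tested genes was 0.04 as deposited, 0.10 on TPM and -0.01 after median-of-ratios rescaling, and 58.3%, 66.6% and 51.1% of calls were higher. Vldlr, which did not pass as reported, changed sign, to -0.008 after that rescaling, whose factors were 1.0107 to 1.0408 in Upf2cKO and 0.9788 to 0.9902 in controls and so lower every Upf2cKO value against the controls. Of the other values of named genes under an alternative, 2211 kept their direction and their side of the threshold and 2 now passed. For the lists 617 did so, 15 lost the call and 7 gained it.

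With the replicate number as a block, 10549 genes changed, 6126 higher and 4423 lower, with 10136 calls shared, 305 lost and 413 gained, and 20 lists passed. The correlation of the deviations of libraries with the same number was 0.052 to 0.523 over the 4 pairs, and 5 of 8 libraries correlated best with their own number, and since not every pair was above 0.1 the number was not taken to pair the samples. The planned tests on counts, by edgeR and DESeq2, were not run because whole reads were not recovered from the rounded values. At the depth of these libraries, genes under 0.5 CPM were left out and their changes were not examined except with no filter, which tested all genes with a value above 0.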

Other observations

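All tests in this part were chosen after the values had been seen. Besides the lists fixed beforehand, 25 gene families were looked at, mostly by the start of the gene symbol, and 24 had at least 5 measured genes. The families described here, and the genes named in them, were picked after their values were seen, with adjustment over all 24. Genes of cholesterol and fatty acid synthesis fell together, with 27 of 31 lower and 3 higher, a median 1.69-fold fall (camera adjusted p = 6.17e-11, but adjusted p = 0.0992 with an estimated correlation). Acat2 fell from 194 ± 4.44 to 91.3 ± 2.49 CPM (SD, n = 4), Sqle, the squalene epoxidase, from 227 ± 7.92 to 117 ± 5.92 CPM and Fdft1, the squalene synthase, from 269 ± 7.38 to 157 ± 2.48 CPM. The median log2 change of that family was -0.76, -0.70 on TPM and -0.81 after median-of-ratios rescaling. Of 35 aminoacyl-tRNA synthetase genes, 24 were higher and 4 lower (camera adjusted p = 0.000133, but adjusted p = 0.0992 with an estimated correlation), including the mitochondrial enzymes Ears2 (14.0 ± 0.615 to 35.2 ± 1.34 CPM) and Tars2 (37.4 ± 0.867 to 78.0 ± 3.28 CPM). Of these genes, 4 are in the lists fixed beforehand.

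Ribosomal protein genes were lower in 65 and higher in 3 of 77, with a median 1.33-fold fall (camera adjusted p = 3.8e-16, but adjusted p = 0.284 with an estimated correlation), and Rps27a went from 330 ± 11.3 to 219 ± 8.14 CPM. Their pseudogenes can share reads, so single values are uncertain. Of 17 olfactory, vomeronasal and taste receptor genes, 14 were higher and 1 lower (camera adjusted p = 0.000513, but adjusted p = 0.144 with an estimated correlation), with Tas1r3 going from 1.41 ± 0.158 to 16.3 ± 0.752 CPM and Olfr461 from 0.295 ± 0.0173 to 4.41 ± 0.328 CPM. These families kept their direction on TPM and after median-of-ratios rescaling. In all, 11 of the 24 families passed with the preset correlation and 0 with an estimated one. The other 7 that passed were complex I genes (32 of 47 lower, 7 higher), proteasome subunits (18 of 36 lower, 6 higher), small nucleolar RNA host genes (8 of 12 higher, 3 lower), axonemal dynein heavy chains (14 of 15 higher, 1 lower) and genes named Ccdc (58 of 109 higher, 15 lower), Cfap (14 of 21 higher, 1 lower) and Cep (21 of 37 higher, 6 lower). The lists fixed beforehand already hold 9 of these dynein heavy chains, 5 host genes, 5 Cfap, 4 Ccdc and 3 Cep genes. To that extent these families repeat results given above.

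For the rise of the motile cilia genes, more choroid plexus in the dissected tissue was argued against as the whole cause, since with the log2 level of Ttr as a covariate the list's median log2 change was 0.782 (interval 0.606 to 1.142), against 0.77 without it. A general rise of genes of low level was argued against as well, since random lists of the same level had a median of 0.152 (interval -0.057 to 0.405). Retention of transcripts annotated as NMD targets was argued against as the whole cause, since the 33 members with no such transcript had a median of 0.652 (interval 0.579 to 1.039), beside 1.107 for the 9 with one. Whether more multiciliated cells or a higher level per cell may underlie the rise stays open, and NMD of transcripts that the annotation does not mark was not tested.

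The joint rise of the interneuron and microglia markers may reflect a loss of cells of the Emx1 lineage, in which case markers of every other cell type would rise alike. Endothelial markers fell, and the interneuron median lay 0.893 above the endothelial one on the log2 scale (interval over genes, not libraries, 0.791 to 0.992). That explanation was argued against as the whole cause only if the vessels did not shrink with the tissue, which was not tested. Whether there were more microglia of unchanged state could not be judged, since the homeostatic genes were grouped after the values had been seen. The 12 homeostatic microglia genes, 6 of them in the lists fixed beforehand, had a median log2 change of 0.783. That of the other microglia markers lay 0.943 above it (interval over genes, not libraries, 0.439 to 1.732). More microglia or macrophages, of an unchanged or a changed state, together with a change in the interneurons or the vessels themselves, stay open as hypotheses. Of the homeostatic genes 7 were higher and 0 lower (camera adjusted p = 0.0759, and adjusted p = 0.693 with an estimated correlation).

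The 8 libraries can be split into 4 and 4 in 35 ways. The real split alone gave as many changed genes (1 of 35 splits), higher genes (1 of 35) and lower genes (1 of 35), 10441, 6082 and 4359. The highest count in any other split was 1 for each. Every other split mixes libraries of both groups on each side, so the difference between the groups adds to its spread and few calls could arise. This comparison therefore cannot exclude chance, and 1 of 35 is the smallest share it can give. For the genes with an annotated NMD transcript, the size of the difference from random lists of the same level was 0.136 and the highest of the other splits 0.074 (1 of 35, the real one). Splits that left 3 libraries of a group together hold part of the real difference. The even splits, which balance the groups, gave at most 0.01, so libraries within a group differed little in this measure. Chance was not excluded, since 1 of 35 is the smallest share these splits can give. For the long 3' UTR genes the size of that difference was 0.05 and the highest other 0.054, reached also by an even split with 2 libraries of each group on either side. As many as 4 of 35 splits gave a difference as large, so chance was not excluded, although the median itself, 0.064 in size, was just above the highest other, 0.0623. The number of lists past the threshold was not set apart in this way. As many as 4 of 35 splits gave 19 or more, the highest other 21. The other splits that reached 19 all left 3 libraries of a group together and so hold part of the real group difference. Their count therefore cannot tell chance from that difference. The 16 splits that left 3 libraries of a group together gave up to 21 lists and the 18 even splits up to 12, so camera with the preset correlation also called lists where each side of a split held libraries of both groups evenly.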
